A study of Arabidopsis thaliana with 4 samples.

How the data were processed

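RNA was sequenced from 4 libraries of Arabidopsis thaliana Col-0 plants, 1 library per group. The groups were wild type and a line carrying HSFA4A behind an estradiol-inducible promoter, each treated with 5 µM estradiol for 6 h, with 1 mM H2O2 added or left out. Per the labels' protocols, ribosomal RNA was depleted from total RNA, the RNA was fragmented, and 50-base colour-space reads were obtained on a SOLiD 5500xl instrument.

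The deposited tables hold whole read counts per annotated gene, per the file headers, split into exon, intron and uniquely mapped reads. Per the authors' settings notes deposited with the tables, reads were mapped with strand to annotated genes with at most 2 mismatches, and reads matching more than 10 places were dropped. How reads matching several places were assigned is not stated, so counts of near-identical genes are uncertain. The mapper and the genome build are not given in the sources used here. The deposited normalized expression values are RPKM values that the authors rescaled so that each library sums to 1000000, which is the TPM unit. The median read coverage over a gene's exons is given per gene, per the file headers. A further deposited table gives signed fold values against the untreated wild type, from which the authors removed genes with fewer than 30 gene reads or a normalized value of 0, per their notes. That table was used only to describe the authors' own comparisons.

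Of 33512 features, 33323 were nuclear and 27205 of these had an exon model. A locus was found for 27143, of which 17963 carried it as their name, 8572 in the deposited synonym column, 78 by identical coordinates and 530 by an overlap of at least 0.5 with a gene of the TAIR10.1 annotation that no other feature held. These 27143 features, 26706 of them protein coding, were analysed. Coordinates are those of the authors' files. Reads of ribosomal RNA, transfer RNA, snoRNA, organelle genes, pseudogenes and transposons were counted as classes. Organelle genes were left out of the comparisons. Any nuclear features of the other classes with an exon model and a locus stayed in them, but were not named among the highest and lowest genes.

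The libraries held 1873352 exon reads for wild type, 2116383 for wild type with H2O2, 2571800 for the overexpressor and 2004085 for the overexpressor with H2O2. The main values are exon reads scaled by TMM factors from edgeR 4.0.16 (calcNormFactors, in R 4.3.3), computed on the nuclear protein-coding genes. The factors were 0.983 for wild type, 1.02 for wild type with H2O2, 0.999 for the overexpressor and 1.00 for the overexpressor with H2O2. For each gene the log2 ratio was taken after adding 0.5 to each count, and it has an exact 95% interval (Clopper-Pearson, on the share of the reads of both libraries). Levels have exact Poisson 95% intervals, and the interval of a difference between responses comes from the delta method. With 1 library per group there is no replicate check and no p-value is given. The intervals cover counting error only, and every comparison is one of these libraries, not of the conditions. A gene was tested at a mean count of at least 50 over the libraries compared, and called at a ratio of at least 2-fold. A fold against a library with no read was computed against 3 counts in that library. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.

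The comparisons, thresholds, gene lists and the rule for named genes were fixed before the data were examined. The rule names HSFA4A, the 10 highest and 10 lowest ratios whose interval lies on the side of the direction, up to 4 members with the largest ratios from each list, and HSP17.6A, CRK13, WRKY30 and ZAT6. The last 4 genes are remembered from the study's publication and may have been chosen on these samples. The lists were heat shock factors, small heat shock proteins, large chaperones with co-chaperones, antioxidant enzymes, glutathione transferases, detoxification with mitochondrial stress, stress transcription factors, the MAP kinase cascade, cysteine-rich receptor kinases, abscisic acid and osmotic response, salicylate and camalexin defence, jasmonate, nuclear photosynthesis genes, aliphatic glucosinolate synthesis, auxin response, hypoxia, carbon starvation, the circadian clock, root markers, seed and flower markers, and cell division. A further 7 GO terms were used: response to heat, to hydrogen peroxide, to oxidative stress, to salt stress and to chitin, photosynthesis, and structural constituent of ribosome. The median ratio of a list with at least 3 measured members was placed among 10000 random lists of the same size matched on mean count.

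Many ratios rested on reads piled on a short part of a gene. A gene was said to have concentrated reads in a comparison when, in any library compared, its exon reads gave at least 4 times the median coverage plus 0.5. This measure, a second naming of the 10 highest and 10 lowest genes without concentrated reads, and the values relative to the median of the tested genes were chosen after seeing the data. In the comparisons of a pair of libraries, the second naming also required median coverage, scaled to library size, to move the same way. Alternatives fixed in advance were median-of-ratios scaling, scaling by the exon reads of nuclear genes, the authors' normalized values, minimum mean counts of 10 and 200 and none, a pseudocount of 5, thresholds of 1.5-fold and 3-fold, calls limited to intervals that exclude a fold of 1, and thinning to the shallowest library. Alternatives chosen after seeing the data were TMM factors from genes past the filter, uniquely mapped reads, calls without concentrated reads, those of them whose scaled median coverage also moved the same way, and ratios relative to genes of like mean count. For the 4 remembered genes these were the analysed genes with a mean count within 1.2-fold of theirs, also chosen after seeing the data.

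The calculations were tested on simulated counts with 200 genes changed by known folds. These counts varied by counting error alone, around a mean profile common to all libraries. They held no variation between plants or libraries and no trend with count. The shares called are therefore not error rates of the calls in the real libraries. For H2O2 in wild type, over 8159 genes, 22 of 25 genes raised and 15 of 16 lowered 2.5-fold were called, all 25 raised 4-fold were called, and 0 of 7999 unchanged genes were. For overexpression without H2O2, over 8867 genes, 24 of 25 genes raised and 19 of 19 lowered 2.5-fold and 0 of 8703 unchanged genes were called. For H2O2 in the overexpressor, over 9058 genes, 25 of 25 genes raised and 20 of 23 lowered 2.5-fold and 1 of 8875 unchanged genes were called. For overexpression with H2O2, over 8367 genes, 17 of 17 genes raised and 25 of 25 lowered 2.5-fold and 1 of 8206 unchanged genes were called. For the difference of responses, with changes placed in wild type, over 8639 genes, 22 of 24 raised and 22 of 25 lowered 2.5-fold and 30 of 8452 unchanged genes were called. With changes placed in the overexpressor, over 8631 genes, 25 of 25 raised but only 17 of 23 lowered 2.5-fold were called, the lowest share at that fold, and 22 of 8442 unchanged genes were. In the same tests the 95% intervals held the true value for 95.1% to 95.7% of genes. Gene sequences of the TAIR10.1 assembly were compared with ribosomal and organelle sequence by blastn 2.17.0 for a test in the closing section.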

Results

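The series measured transcripts in Arabidopsis plants 2 weeks old that were wild type or carried an estradiol-inducible copy of HSFA4A, a heat shock transcription factor. Each genotype was sampled after 6 h in 5 µM estradiol alone and after 6 h in estradiol with 1 mM H2O2, which gave 4 groups of 1 library. Reads assigned to genes numbered 7236311 in wild type, 8536560 in wild type with H2O2, 9776801 in the overexpressor and 8184517 in the overexpressor with H2O2. Reads in nuclear protein-coding genes made up 30.1%, 30.6%, 30.9% and 27.5% of these, in the same order. Nuclear ribosomal RNA took 20.2%, 29.8%, 14.7% and 20.9%, and plastid genes took 44.6%, 34.4%, 49.0% and 47.5%. Levels are given as TMM-scaled exon reads per 1000000 (CPM). Changes are given as log2 ratios with 95% counting intervals.

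The library of wild type with H2O2 stood apart from the other 3. In genes with concentrated reads, the reads far exceeded what the median coverage of the gene accounts for. Those with at least 50 exon reads numbered 867 in this library, against 268 in wild type, 455 in the overexpressor and 342 in the overexpressor with H2O2. That number moves with read depth, but the overexpressor library had more exon reads and fewer such genes. Genes with concentrated reads, of any count, held 28.8% of the exon reads of the treated wild-type library, against 11.8%, 14.6% and 10.8% in the other libraries. SYP132, a syntaxin of the plasma membrane, alone took 13.0% of its exon reads, against 4.66%, 5.12% and 3.04%. Reads in introns were 19.2% of the reads of protein-coding genes there, against 14.3%, 15.2% and 11.4%, and 745 analysed genes had no read, against 1561, 972 and 1380. The H2O2 ratio in wild type also moved with expression. Its median was 0.70 among genes with a mean count of 5 to 10 and −0.47 among genes with at least 500, while the H2O2 ratio in the overexpressor went from −0.17 to 0.04. As a result the median log2 ratio of the tested genes was −0.33 for H2O2 in wild type, 0.34 for overexpression with H2O2 and 0.38 for the difference of responses, against 0.04 for H2O2 in the overexpressor and −0.04 for overexpression without H2O2. In the 3 shifted comparisons, values are therefore given relative to the median of the tested genes unless stated otherwise, while genes were called on the unshifted ratio. A gene there that rose or fell with a relative ratio short of 2-fold passed the threshold only with the shift left in. Conversely, a gene that passed 2-fold only on the relative scale was not called.

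**Figure D1:**
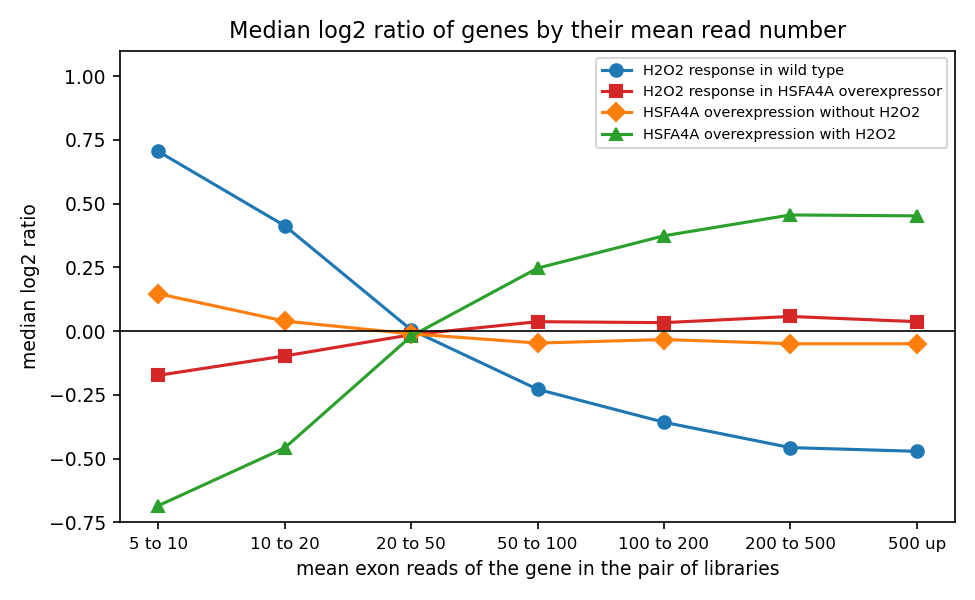
Median log2 ratio of genes (y axis) by mean exon reads per gene (x axis, in bins) for the 4 comparisons of a pair of libraries, each drawn as a line. The lines for H2O2 in wild type and for overexpression with H2O2 run from 0.70 to −0.47 and from −0.68 to 0.45, and the other lines stay between −0.17 and 0.15.

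HSFA4A (AT4G18880, chromosome 4, 10347582 to 10349562) was the gene expressed from the inducible promoter, and its level checks the genotype labels but not the H2O2 labels. It stood at 48.0 CPM in wild type (38.5 to 59.1) and 49.4 in wild type with H2O2 (40.4 to 59.7). In the overexpressor it stood at 3182 (3113 to 3252), and at 2254 (2189 to 2321) in the overexpressor with H2O2. These levels rest on 88, 106, 8144 and 4504 exon reads. The median coverage of its exons was 2, 2, 166 and 98, so the reads were spread along the gene. The log2 ratio to wild type was 6.04 without H2O2 (5.75 to 6.37), and with H2O2 it was 5.17 relative to the median of tested genes (4.90 to 5.47). In wild type the H2O2 ratio of HSFA4A was 0.37 on the relative scale (−0.05 to 0.80), and in the overexpressor, where no shift was removed, it was −0.50 (−0.55 to −0.44). Neither passed 2-fold, and the difference between them was −0.92 relative to the median of tested genes (−1.33 to −0.51).

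Overexpression of HSFA4A without H2O2 asks which transcripts differ when the factor is induced in plants given no oxidant. The medians of the large chaperone and small heat shock protein lists lay above random lists in the overexpressor library, and that of photosynthesis genes below. HSP23.6 (AT4G25200), a small heat shock protein of mitochondria, rose by 3.38 on the log2 scale (2.49 to 4.62), from 4.91 to 53.9 CPM. HSP90.1 (AT5G52640), the heat-inducible cytosolic HSP90, rose by 2.32 (2.16 to 2.48), from 206 to 1026. Among nuclear photosynthesis genes, the Rubisco small subunit gene RBCS1B fell, with a log2 ratio of −1.37 (−1.70 to −1.06).

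In this comparison 164 of 8811 tested genes rose and 77 fell, and 99 of the rising and 25 of the falling genes had concentrated reads. Of 20 large chaperones and co-chaperones measured, 5 rose, 0 fell and 17 lay above the median of all tested genes. Besides HSP90.1 they were ROF2, an immunophilin that binds heat shock proteins, at 1.54 (1.22 to 1.89), the co-chaperone HOP3 at 1.23 (0.94 to 1.52), the disaggregase HSP101 at 1.2 (0.88 to 1.55) and the cytosolic HSP70 at 1.06. The list's median was 0.37 above that of all tested genes, at percentile 100 of random lists. Of 4 small heat shock proteins measured, HSP23.6 rose and HSP17.6B had a log2 ratio of 0.99, with a median 0.78 above all tested genes, at percentile 99.9. At a minimum mean count of 10, 11 small heat shock proteins were measured and 6 rose, at percentile 100. Of 3 other heat shock factors measured, HSFA1B rose by 3.05, but its reads were concentrated and its median coverage was 1 in the overexpressor. The median of these 3 was at percentile 97.1.

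None of the 22 nuclear photosynthesis genes lay above the median of tested genes. Of these, 3 fell, RBCS1B, RBCS2B at −1.08 (−1.28 to −0.88) and the light-harvesting gene LHCB4.2 at −1.07 (−1.44 to −0.71), and RBCS1A had a ratio of −0.91. RBCS1B and RBCS2B are near-identical copies, and 68.1% and 63.2% of their reads mapped uniquely, so their counts are uncertain. The list's median was −0.64 relative to all tested genes, at percentile 0. Outside the list, CA2, a carbonic anhydrase, fell, at −1.36 (−1.78 to −0.96), TLP18.3, which acts in photosystem II repair, at −1.35, and GLDP1, of photorespiratory glycine breakdown, at −1.3 (−1.53 to −1.07). The lipid transfer protein gene LTP3 fell by 1.85 (−2.49 to −1.27) and LEA14 by 1.3. Aliphatic glucosinolate genes, which make methionine-derived defence compounds, had a median of −0.47 at percentile 0.05. Of 9 measured, 1 fell, CYP79F1 at −1.02 (−1.46 to −0.60).

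Detoxification and mitochondrial stress genes had a median of 0.30 at percentile 98.5. Of 8 measured, 1 rose, the glucosyltransferase UGT75B1 at 1.25 (0.67 to 1.91), and the alternative oxidase AOX1A had a ratio of 0.79 and NAC013 of 0.98. Stress transcription factors had a median of 0.36 at percentile 97.8, and 0 of 6 passed 2-fold, with WRKY33 at 0.57 and WRKY18 at 0.46. Antioxidant enzymes had a median of −0.19 at percentile 1.59, and 0 of 20 passed 2-fold, with the iron superoxide dismutase FSD1 at −0.99 (−1.1 to −0.88) and the catalase CAT3 at −0.85. Abscisic acid and osmotic response genes had a median of −0.44 at percentile 0.31, and 0 of 6 passed 2-fold. These 2 medians were inside the middle 95% of random lists at a minimum mean count of 200, at 21.1 and 4.8. The lists inside the middle 95% of random lists were glutathione transferases at percentile 90.73, the MAP kinase cascade at 39.9, jasmonate at 38.7, auxin response at 37.5, hypoxia at 69.1, the circadian clock at 42.0 and root markers at 10.4. Cysteine-rich receptor kinases, at 4.6, had CRK11 up at 1.04 and CRK19 down at −1.27. In the hypoxia list 1 of 3 rose, LBD41 at 1.35, and in carbon starvation 1 of 2, AT3G15450 at 1.18. The 2 salicylate genes measured did not pass 2-fold.

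Genes annotated to the response to heat had 8 rising and 0 falling members of 84, with a median 0.13 above all tested genes, at percentile 100. Those for response to chitin had a median of 0.47 at percentile 100. Photosynthesis genes by annotation stood at −0.57 and ribosomal protein genes at −0.11, both at percentile 0. Response to hydrogen peroxide, with 3 of 24 rising, was at percentile 17.81 with a median of −0.07, but at a minimum mean count of 200 its 8 genes were at 98.3 with 0.20. Response to oxidative stress was at 11.2 and response to salt stress at 5.48. Outside the lists, the rising genes without concentrated reads included TEJ, a poly(ADP-ribose) glycohydrolase, at 2.12, ATKDSA2 at 2.21, CYP71B37 at 1.89, the transporter gene WBC19 at 1.78 and ACS7, an enzyme of ethylene synthesis, at 1.62. The highest ratios by rule other than HSFA4A, from 4.84 to 6.99, all had concentrated reads. Among them were AT4G04990 at 6.99 and CYP71B9 at 6.37. The lowest were AT3G45577 at −5.37 and EMB140 at −5.02, both with concentrated reads.

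**Figure D2:**
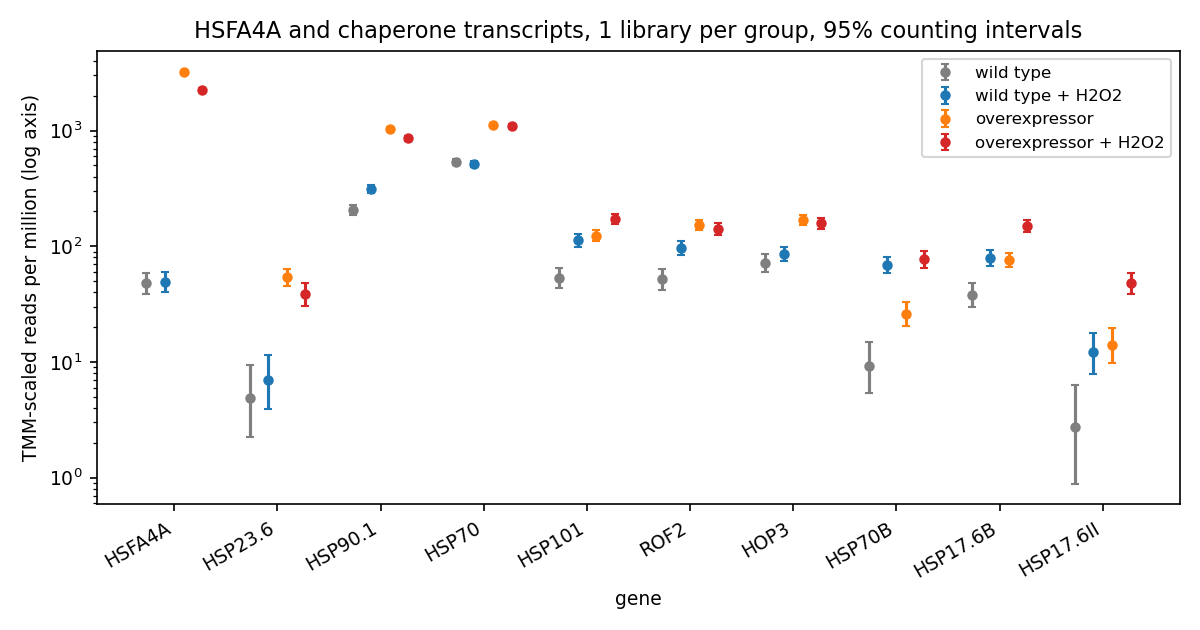
Levels of HSFA4A and 9 chaperone genes in the 4 libraries, as CPM on a log axis, with bars for 95% counting intervals. HSP90.1 stands at 206, 311, 1026 and 857 in wild type, wild type with H2O2, the overexpressor and the overexpressor with H2O2, and HSP70B at 9.27, 69.4, 26.2 and 77.1.

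H2O2 in wild type asks which transcripts respond to the oxidant when HSFA4A is not induced. The median of the large chaperone list lay above random lists in the treated library, and those of the jasmonate and glucosinolate lists below, but the chaperone and jasmonate calls depended on the minimum count. HSP70B (AT1G16030), a stress-induced HSP70, rose by 3.20 relative to the median of tested genes (2.51 to 4.05), from 9.27 to 69.4 CPM. HSP101 rose by 1.4 (1.06 to 1.75) and HSP17.6B by 1.38 (0.97 to 1.81). The copper/zinc superoxide dismutase of plastids, CSD2 (AT2G28190), fell, at −1.76 (−2.37 to −1.21).

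Of 7999 tested genes 259 rose and 321 fell, and 218 of the rising and 25 of the falling genes had concentrated reads. With TMM factors from the genes past the filter, chosen after seeing the data, the counts were 475 and 57. Among 20 large chaperones, HSP70B and HSP101 rose, 0 fell and ROF2 had a relative ratio of 1.21 (0.86 to 1.59). Their median was 0.15 above all tested genes, at percentile 99.4, but at a minimum mean count of 200 it was 0.08 at 87.3, with 0 of 13 rising. Only 2 small heat shock proteins had enough reads, and HSP17.6B was the one that rose. At a minimum mean count of 10, 6 of 12 rose and 0 fell, at percentile 99.5. The 2 other heat shock factors measured did not pass 2-fold.

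Jasmonate genes had a median of −0.64 at percentile 0.04, and 3 of 6 fell, but with no minimum count 21 genes had −0.03 at 40.25. They were the lipoxygenase LOX2 at −1.12 (−1.51 to −0.74), the repressor JAZ6 at −0.87 and the synthesis gene AOS at −0.69. MYC2, the main jasmonate transcription factor, had a relative ratio of −0.60. Aliphatic glucosinolate genes had a median of −0.34 at percentile 0.93, and 2 of 9 fell, UGT74C1 at −1.14 (−1.76 to −0.58) and CYP83A1 at −0.69. Stress transcription factors were at percentile 98.0 with a median of 0.65, but the 1 of 5 that rose, ERF6 at 4.50, had concentrated reads. Cysteine-rich receptor kinases were at percentile 98.4 over 3 genes with a median of 0.88, where CRK19 fell, at −1.48 (−2.03 to −0.99). CRK18, at 1.18, had concentrated reads. The medians of these 2 lists were at 87.9 and 89.85 at a minimum mean count of 10.

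Antioxidant enzymes had a median of −0.19 at percentile 6.47, and CSD2 was the 1 of 20 that fell. The catalase CAT2 and the dehydroascorbate reductase DHAR1 each had a relative ratio of −0.54. Among 10 glutathione transferases, GSTU13 fell, at −0.87, and GSTU17 rose, at 1.99, with concentrated reads, and the list was at percentile 58.6. The detoxification list was at percentile 35.7, the MAP kinase cascade at 34.4, abscisic acid and osmotic genes at 28.5, photosynthesis genes at 87.0, auxin response at 91.0, the circadian clock at 16.01 and root markers at 86.1. The clock gene PRR5 fell, at −0.75. PR2, the only salicylate gene measured, rose by 1.85, and IAA19, 1 of 3 auxin response genes, by 1.91, both with concentrated reads. No hypoxia gene and no carbon starvation gene passed 2-fold.

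By annotation, ribosomal protein genes had a median of −0.18 at percentile 0, with 2 rising and 17 falling of 265, but at a minimum mean count of 200 it was −0.05 at 11.65. Response to heat was at percentile 95.7, hydrogen peroxide at 75.2, or 98.6 at a minimum of 10, oxidative stress at 8.81, or 0 at that minimum, salt stress at 11.3, chitin at 83.0 and photosynthesis at 59.2. Outside the lists, DOX1, a fatty acid dioxygenase, rose by 1.62 (1.31 to 1.96). The major latex protein-like gene MLP328 was at −1.61 (−2.11 to −1.16), CPZ at −1.76 (−2.52 to −1.11), RCI2A at −1.36 (−1.81 to −0.95) and PAI1, an enzyme of tryptophan synthesis, at −1.22, and each of these fell. All 10 of the highest ratios by rule had concentrated reads. They included AT3G01230, with 10 and 3489 reads, CASP4, with 4 and 1284, and AGP23, with 0 and 133 reads, at least 37.8-fold higher before the shift is removed. Among the lowest was EMB140, at −4.95, with 4454 and 134 reads.

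H2O2 in the overexpressor asks the same question with HSFA4A induced. The medians of the small heat shock protein, antioxidant and photosynthesis lists lay above random lists with H2O2, the antioxidant one not at a minimum count of 200. HSP17.6II rose by 1.76 on the log2 scale (1.21 to 2.37), HSP17.4 by 1.59 (0.99 to 2.25), HSP17.6A (AT5G12030) by 1.57 (0.94 to 2.25) and HSP70B by 1.55 (1.14 to 1.99). The glutathione peroxidase GPX6 rose by 1.04 (0.72 to 1.37) and the light-harvesting gene LHCB4.2 by 1.22 (0.87 to 1.58).

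Of 9150 tested genes 193 rose and 179 fell, and 102 and 122 of these had concentrated reads. Of 8 small heat shock proteins 3 rose and 0 fell, with a median 0.77 above all tested genes at percentile 100, and HSP17.6B had a ratio of 0.98. Among 21 large chaperones HSP70B was the 1 that rose and HSP101 had a ratio of 0.48, and the list was at percentile 26.7. All 22 photosynthesis genes lay above the median of tested genes, with a median of 0.60 at percentile 100, and LHCB4.2 was the 1 that rose. LHCA2 and RBCS3B each had a ratio of 0.81. Antioxidant enzymes had a median of 0.32 at percentile 100, GPX6 was the 1 of 20 that rose, and CAT2 had a ratio of 0.82. The antioxidant median was 0.15 at 95.35 at a minimum mean count of 200, with 0 of 11 rising. Aliphatic glucosinolate genes had a median of 0.30 at percentile 99.0 and abscisic acid and osmotic genes one of 0.29 at percentile 98.1, or 93.8 at that minimum. None of their 8 and 6 members passed 2-fold, and CYP79F1 had a ratio of 0.97.

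The jasmonate gene LOX4 rose by 1.55 (1.05 to 2.07), 1 of 7 measured, and the list was at percentile 85.2. Other heat shock factors were at percentile 79.4, with 1 of 3 falling, HSFA1B at −3.71 with concentrated reads. Glutathione transferases were at percentile 94.8, detoxification genes at 91.6, stress transcription factors at 59.7, the MAP kinase cascade at 53.0, cysteine-rich receptor kinases at 84.4, auxin response at 64.6 and the circadian clock at 85.8. No member of these 7 lists passed 2-fold. Root markers were at 94.7, with THAS, the thalianol synthase, rising by 1.16 (0.72 to 1.62). The salicylate gene PR2 fell, at −1.02, with concentrated reads, the carbon starvation gene AT3G15450 rose by 1.24 (0.84 to 1.66), and the 2 hypoxia genes measured did not pass 2-fold, with LBD41 at −0.95. By annotation, response to oxidative stress and photosynthesis were at percentile 100, salt stress at 99.9, hydrogen peroxide at 99.5, ribosomal protein genes at 99.3, heat at 98.0 and chitin at 20.4. With at least 200 reads, oxidative stress was at 94.7, ribosomal protein genes at 94.6 and heat at 80.2, and hydrogen peroxide was inside the middle 95% too. Outside the lists, TRB2, a telomere-binding protein, rose by 2.18, VPS26A, of the retromer, by 2.06, and the auxin response factor ETT by 1.80. TEJ fell, at −1.94 (−2.51 to −1.44), as did ARF18 at −1.84 and VIM3, a methylated-DNA binding protein, at −1.77. The 10 highest ratios by rule, led by RHS16 at 8.06, and the 10 lowest, led by AT1G52315 at −6.52, all had concentrated reads.

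Overexpression with H2O2 asks how the genotypes differ once both receive the oxidant. The medians of the jasmonate, detoxification and small heat shock protein lists lay above random lists in the overexpressor, the jasmonate one not at lower minimum counts. Relative to the median of tested genes, HSP17.6II rose by 1.63 (1.01 to 2.33), HSP90.1 by 1.12 (0.99 to 1.25) and HSP70 by 0.77 (0.67 to 0.88). JAZ6 rose by 1.23 (0.67 to 1.86) and CSD2 by 1.12 (0.53 to 1.76). The carbonic anhydrase BCA5 rose by 2.08 (1.72 to 2.47).

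In all, 482 of 8348 tested genes rose and 378 fell, and 107 and 312 of these had concentrated reads. With TMM factors from the genes past the filter the counts were 198 and 606. Jasmonate genes had a relative median of 0.75 at percentile 100, and 4 of 7 rose, JAZ6, AOS at 0.95, LOX4 at 0.92 and LOX2 at 0.75. At a minimum mean count of 10, 15 jasmonate genes had a median of 0.08 at percentile 69.35. Detoxification genes had a median of 0.72 at percentile 100, and 4 of 7 rose, the glucosyltransferase UGT73B2 at 1.03 (0.54 to 1.56), the alternative NADH dehydrogenase NDB2 at 0.81, and AOX1A and OPR1 at 0.72 each. Of 20 antioxidant enzymes 3 rose, CSD2, GPX2 at 0.97 and GPX6 at 0.78, with a median of 0.33 at percentile 99.7, but at a minimum of 200 it was 0.04 at 66.8, with 0 of 8 rising. Small heat shock proteins had a median of 0.58 at percentile 99.6, or 97.1 relative to genes of like mean count, with HSP17.6II and HSP17.8 at 0.77 as the 2 of 5 that rose. HSP90.1 and HSP70 were the 2 of 21 large chaperones that rose. That list was at percentile 97.53, or 93.5 at a minimum of 10, and HOP3 had a relative ratio of 0.54. Circadian clock genes were at percentile 99.6, or 76.7 at a minimum of 10, with PRR5, 1 of 5, rising by 0.88.

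Nuclear photosynthesis genes stood at 0.01 relative to all tested genes, at percentile 8.77, or 1.3 without concentrated reads, and 0 of 22 passed 2-fold. Glutathione transferases were at percentile 92.9, stress transcription factors at 32.4, the MAP kinase cascade at 66.3, cysteine-rich receptor kinases at 34.01, abscisic acid and osmotic genes at 64.3, glucosinolate genes at 90.9, auxin response at 12.6 and root markers at 27.8. Of 14 root markers 7 fell at a minimum of 10, at percentile 0. Within them WRKY18 rose by 1.15 (0.57 to 1.79), MPK3, a stress-activated MAP kinase, by 0.80, ERD1 by 0.83, GSTU13 by 0.84 and UGT74C1 by 1.2 (0.64 to 1.80). ERF6 at −5.31, GSTU17 at −2.69, PR2 at −2.64 and IAA19 at −2.33 fell with concentrated reads. Of 2 carbon starvation genes both rose, AT3G15450 at 1.24 and DIN10 at 0.73, and the only heat shock factor and the only hypoxia gene measured did not pass 2-fold. By annotation, response to heat, salt stress and chitin were at percentile 99.9, hydrogen peroxide at 97.3, oxidative stress at 97.1, ribosomal protein genes at 86.4 and photosynthesis at 7.12. Salt stress was, at a minimum of 200, at 96.75 and chitin, over 3 genes, at 71.5. Outside the lists, STT3B, of protein glycosylation, rose by 1.87 (1.56 to 2.2) and HR4, of a disease-resistance family, by 1.71 (1.15 to 2.35). UBC29, a ubiquitin-conjugating enzyme, fell, at −2.15 (−2.89 to −1.51), as did ABI2, a phosphatase of abscisic acid signalling, at −1.83 (−2.34 to −1.37), and the arabinogalactan gene AGP9 at −1.41. Except for HSFA4A, the 10 highest and 10 lowest ratios by rule had concentrated reads. AGP23, with 133 reads in wild type and 0 in the overexpressor, was at least 41.3-fold lower before the shift is removed.

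The difference of the H2O2 responses between genotypes asks which genes respond more, or less, when HSFA4A is induced. The medians of the photosynthesis, antioxidant and jasmonate lists lay above random lists, and that of large chaperones below. Relative to the median of tested genes, CSD2 differed by 1.93 (1.24 to 2.63), GPX6 by 1.51 (1.03 to 1.98), CAT2 by 1.31 (0.86 to 1.76), LOX2 by 1.34 (0.86 to 1.82) and LHCB4.2 by 1.27 (0.79 to 1.75). HSP70B differed by −1.70 (−2.52 to −0.87) and ROF2 by −1.38 (−1.79 to −0.96).

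The difference passed 2-fold upward for 1058 and downward for 401 of 8654 tested genes, and 104 and 312 of these had concentrated reads. With TMM factors from the genes past the filter the counts were 370 and 709. Of 22 photosynthesis genes 12 passed upward, with a median of 0.68 at percentile 100, among them RBCS2B at 1.06. Antioxidant enzymes had 8 of 20 upward and a median of 0.43 at percentile 99.8, jasmonate genes 3 of 7 and 0.57 at percentile 99.1, or 92.45 with no minimum count, and glucosinolate genes 4 of 9 and 0.55 at percentile 99.5, with UGT74C1 at 1.42. Large chaperones had a median of −0.19 at percentile 0.36, and HSP70B was the 1 of 21 called downward. HSP90.1 had a relative difference of −1.24 (−1.44 to −1.04) and HSP23.6 one of −1.34. These 2 genes and ROF2 passed 2-fold on the relative scale, but were not called because they fell short of it with the shift left in. Other heat shock factors were at percentile 2.12 over 3 genes, or 25.6 at a minimum of 10, with HSFA1B at −2.97 and concentrated reads.

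Detoxification genes were at percentile 96.0, with 2 of 8 upward, one of them NDB2 at 1.21. The list of abscisic acid and osmotic genes was at 97.1 with 3 of 6 upward, the clock at 95.3 with PRR5 at 1.15, small heat shock proteins at 8.92, glutathione transferases at 34.7 with GSTU13 at 1.36, stress transcription factors at 23.0, the MAP kinase cascade at 77.7, cysteine-rich receptor kinases at 22.8 with CRK19 at 1.32, auxin response at 19.6 and root markers at 76.1. The hypoxia gene LBD41, a transcription factor, was called downward at −2.17 (−3.05 to −1.3), and 0 of 2 carbon starvation genes were called. By annotation, photosynthesis was at percentile 100, ribosomal protein genes at 99.9, salt stress at 99.6, oxidative stress at 94.9, hydrogen peroxide at 33.9, chitin at 7.29 and heat at 3.95. At a minimum of 200, salt stress was at 91.95 and ribosomal protein genes at 88.75. Outside the lists, BCA5 differed by 2.12 (1.64 to 2.61), CPZ by 1.82 (1.04 to 2.61), VIM3 by −2.26 and ARF18 by −2.19.

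**Figure D3:**
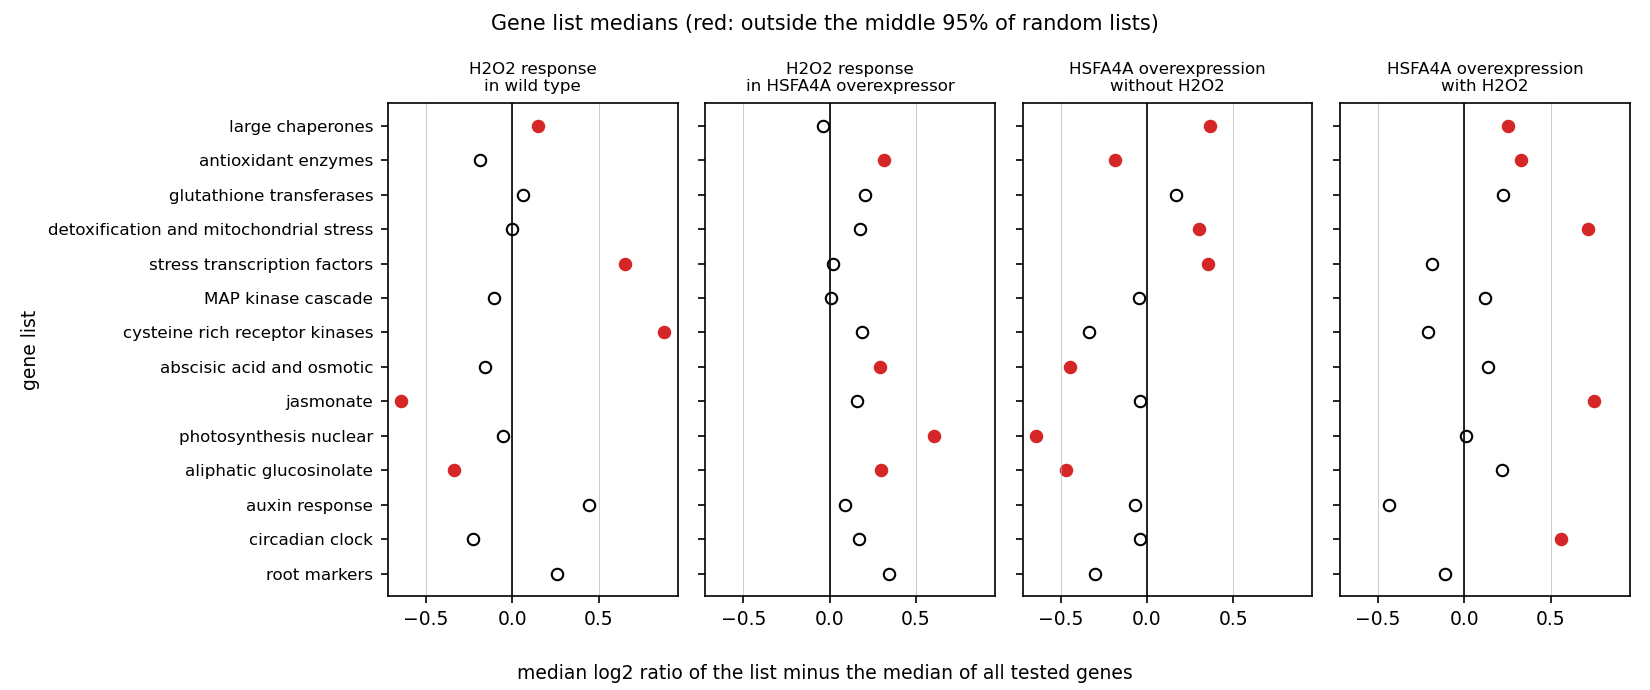
Median log2 ratio of 14 gene lists minus the median of all tested genes (x axis) in the 4 comparisons of a pair of libraries, with points in red where the median lay outside the middle 95% of random lists. Photosynthesis genes stand at −0.64 for overexpression without H2O2 and 0.60 for H2O2 in the overexpressor, and jasmonate genes at −0.64 for H2O2 in wild type and 0.75 for overexpression with H2O2, and each of these pairs of values shares a library.

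Over all comparisons, 30 of 78 gene-list medians and 17 of 35 annotation medians lay outside the middle 95% of random lists. These are not separate results. The comparisons share 4 libraries, so 1 library out of place can put the same list outside in several of them. Random lists also draw genes singly, while members of a list may move together. None of the 9 seed and flower markers and none of the 12 cell division genes had enough reads in any comparison. The 4 genes remembered from the study, whose direction is not independent evidence, mostly had too few reads. HSP17.6A had 3 reads in wild type, 56 in wild type with H2O2, 30 in the overexpressor and 70 in the overexpressor with H2O2. Since the ratios of genes with few reads moved with count, the values of these 4 genes are given relative to the median of genes of like mean count. That of HSP17.6A was 3.74 (2.33 to 6.27) for H2O2 in wild type and 2.62 (1.14 to 5.18) for overexpression without H2O2, both untested. With H2O2, its overexpression ratio of 0.20 (−0.32 to 0.74) did not pass 2-fold, and its difference of responses, untested, was −2.26 (−3.94 to −0.59). The zinc finger gene ZAT6, CRK13 and WRKY30 were untested throughout, on at most 37, 41 and 10 reads in any library. Without H2O2 their overexpression ratios were 1.24 (0.28 to 2.4), 1.1 (0.08 to 2.34) and 1.44 (−0.54 to 4.92). For H2O2 in wild type the intervals of all 3 included 0, with 0.79 (−0.23 to 1.99), 0.75 (−0.32 to 2.01) and 0.85 (−1.24 to 4.36). In the overexpressor the H2O2 ratios were 0.03 (−0.72 to 0.77), 0.77 (0.07 to 1.5) and −2.28 (−8.23 to 0.02), and for overexpression with H2O2 they stood at 0.28 (−0.52 to 1.1), 0.82 (0.08 to 1.61) and −1.61 (−7.58 to 0.79). Their differences of responses, −0.91 (−2.13 to 0.30), −0.22 (−1.45 to 1.01) and −2.94 (−6.14 to 0.26), had intervals that included 0 too.

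Across genes, the H2O2 ratios in wild type and in the overexpressor, which share no library, had Pearson r −0.06 and Spearman rho −0.10 over 7621 genes. Of the genes called, 9 rose in both, against 1.65 by chance, and 3 fell in both, against 3.70, while 14 rose in wild type and fell in the overexpressor, against 1.68. Without genes with concentrated reads, these counts were 3, 1 and 2, against 0.206, 0.924 and 0.0826 by chance. The overexpression ratios without and with H2O2 had r 0.10 and rho 0.09 over 7826 genes, but r turned to −0.0132 at a minimum mean count of 10 and −0.0473 with none. Among the genes called, 16 rose in both, against 3.78, 12 fell in both, against 1.87, and 9 rose without and fell with H2O2, against 2.32. Without concentrated reads these were 11, 1 and 0, against 1.85, 0.196 and 0.186, so most of the shared falls were of genes with concentrated reads. H2O2 in wild type and overexpression without H2O2 share the untreated wild-type library and had r 0.35 and rho 0.31 over 7687 genes. There 15 rose in both, against 0.992 by chance, and 24 fell in both, against 3.16. Without concentrated reads these were 3, against 0.0817, and 14, against 2.07. Their covariance was 0.0703, against 0.0229 in simulated unchanged libraries sharing that control, where r was 0.575. The chance counts take both comparisons as independent, and neither they nor the simulation allow for a deviation of the shared library. Such a deviation moves both ratios the same way, so it cannot be told apart here from a change common to H2O2 and overexpression. Genes are not independent replicates, so no p-value is given.

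The authors' own table held 16555 genes, with folds against untreated wild type. By their values 1647 genes were at least 2-fold higher and 757 at least 2-fold lower in wild type with H2O2, 861 and 333 in the overexpressor, and 836 and 541 in the overexpressor with H2O2. Their fold for HSFA4A was 1.04, 67.9 and 48.9, in that order. Recomputed from the deposited normalized values, 16499 of 16499, 16491 of 16492 and 16478 of 16478 of the folds came within 1%.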

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

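The test of the trend with mean count in the overexpressor, those of photosynthesis genes against all tested genes and with H2O2 and that of chaperone genes in the treated libraries were chosen only after the result was seen.

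A difference between groups set 3 lists apart, and with 1 library per group none of these differences was tested. Aliphatic glucosinolate genes had a median H2O2 ratio of −0.34 in wild type, at percentile 0.93 of random lists, and 0.30 in the overexpressor, at percentile 99.0, which differ by 0.638. Ribosomal protein genes had −0.18 at percentile 0 and 0.05 at percentile 99.3, which differ by 0.227, but at a minimum mean count of 200 both lay inside the middle 95% of random lists, −0.05 at 11.65 and 0.02 at 94.6. Antioxidant enzymes had a median overexpression ratio of −0.19 without H2O2, at percentile 1.59, and 0.33 with H2O2, at percentile 99.7, which differ by 0.513, but at that minimum both lay inside it too, −0.11 at 21.1 and 0.04 at 66.8 over 8 genes each. All of these medians are relative to the tested genes.

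Read classes other than nuclear protein-coding genes gave 3 further signals above the untreated wild type. Nuclear transfer RNA genes held 509 reads in wild type, 2785 in wild type with H2O2, 1703 in the overexpressor and 805 in the overexpressor with H2O2. As shares of all gene reads, the treated wild type stood at 4.64 times and the untreated overexpressor at 2.48 times the untreated wild type. Pseudogenes and transposons held 1.196% of gene reads in wild type and 2.15% in wild type with H2O2, a ratio of 1.80.

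The first pattern weighed is the treated wild-type library, where genes of low count were higher and genes of high count lower. Ribosomal or organelle reads matching part of a gene were argued against only for genes with at least 50 exon reads in this library, since only these were searched. Of 866 of its 867 genes with concentrated reads, 0.808% held a stretch of ribosomal or organelle sequence, against 0.365% of 7402 other genes. Genes with fewer reads, among which the rise at low count lies, were not searched, so this source stays open for them. An H2O2 effect alike in both genotypes would put the trend in the overexpressor too. The median H2O2 ratio at a mean count of 5 to 10 minus that at 500 or more was −0.21 in the overexpressor and 1.18 in wild type, against 0.196 between the untreated libraries. The treated overexpressor library thus lacked the trend. These values restate the trend given above, and with 1 library per group an effect masked in that library cannot be excluded. Reads spread evenly over genes could not be told apart from other sources, since the top 5% of 1970 genes nearly silent elsewhere held 30.8% of their 4670 reads, between the bounds set in advance. An H2O2 effect in wild type alone and a fault in preparing this library stay open, as each group has 1 library.

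A second pattern is the lower level of nuclear photosynthesis genes in the untreated overexpressor. Against lists matched on exon length as well as mean count, the median of the 22 genes, −0.68, was at percentile 0, which argues against a length effect. The other 4 scalings gave −0.69 to −0.64 but moved all genes by at most 0.0441 and decide nothing, while the median of −0.64 relative to all tested genes, which a factor per library cannot move, argues against scaling. With H2O2 the median was 0.010 relative to the tested genes and −0.11 relative to genes of like mean count, and whether HSFA4A lowers these genes whatever the treatment cannot be told apart, because the treated wild-type library carries the trend above. An effect of HSFA4A in untreated plants may underlie the pattern, as a hypothesis, and a difference in growth or harvest, or a fault in either untreated library, stays open.

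The third pattern is the higher level of chaperone genes in the untreated overexpressor. With uniquely mapped reads the median log2 ratio of the 6 called genes was 1.38, as with all reads, which argues against reads shared between near-identical genes. In the comparison of the treated libraries, which shares no library with this one, the median of the same 6 genes was 0.65 relative to the tested genes and 6 of 6 lay above 0. That argues against an untreated wild-type library out of place as the only cause, mainly through HSP23.6 at 2.09, HSP90.1 at 1.12, HSP70 at 0.77 and HOP3 at 0.54. ROF2, at 0.21, and HSP101, at 0.28, add little. Genes with mean counts of 200 to 500, as theirs, had a median of 0.46 in that comparison, against 0.34 for all tested genes. The treated wild-type library carries the trend above, so a deviation of that library in these genes stays open. Induction by HSFA4A is a candidate explanation, as a hypothesis, and a difference between the plants used for each genotype stays open.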

How the results depend on the processing

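The alternatives TMM on genes past the filter, uniquely mapped reads, genes without concentrated reads, median coverage moving the same way and genes of like mean count were chosen after seeing the data. No paired analysis was possible because each group has 1 library and every replicate number is 1. With the authors' normalized values, median-of-ratios scaling, scaling by total exon reads, a pseudocount of 5 and uniquely mapped reads, each of the 17 main results stayed within the bounds set for it, as did the 10 counts with intervals that exclude a fold of 1 and the 10 after thinning. A count of called genes moved if it changed by more than 1.5-fold. All 10 counts moved at thresholds of 1.5-fold and 3-fold, as did all 15 main results at a minimum count of 200. At a minimum of 10 there were 12 moved, 1 reversed and 2 kept, and with none 11 moved, 1 reversed and 3 kept. TMM on genes past the filter moved 7 and kept 10, genes of like mean count moved 6 and kept 9, and leaving out concentrated reads moved 7 and kept 8. The coverage rule moved 6 and kept 2. Among other values, TMM on genes past the filter moved 50 and kept 528, a pseudocount of 5 moved 10 and kept 568, and uniquely mapped reads moved 3 and kept 575. A minimum count of 10 moved 7 and kept 40, one of 200 moved 16 and kept 14, and none moved 10 and kept 37. Genes of like mean count moved 3 and kept 44, and leaving out concentrated reads moved 1 and kept 44. Counts below give higher, then lower, genes.

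At 1.5-fold there were 545 and 1997 for H2O2 in wild type, 605 and 448 for H2O2 in the overexpressor, 467 and 637 for overexpression without H2O2, 2277 and 704 for overexpression with H2O2, and 2987 and 758 for the difference. At 3-fold, in the same order, there were 136 and 16, 107 and 94, 93 and 12, 139 and 178, and 214 and 208. At a minimum mean count of 10 there were 1912 and 870, 651 and 886, 852 and 464, 1184 and 2325, and 2117 and 2708. At a minimum of 200 there were 66 and 46, 50 and 36, 42 and 19, 90 and 93, and 245 and 79. With no minimum there were 4973 and 1464, 1958 and 2854, 2872 and 1681, 1799 and 5380, and 3222 and 6376.

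Of 78 gene-list medians in the main analysis 30 lay outside the middle 95% of random lists, and 17 of 35 annotation medians. At a minimum of 200 only 22 and 34 medians had enough genes, and 6 and 11 of them lay outside. Of the 30, 13 had enough genes there and 6 stayed outside the same way, and of the 17, 8 did. The 7 gene-list calls lost were large chaperones for H2O2 in wild type and for overexpression with H2O2, antioxidant enzymes for H2O2 in the overexpressor and for overexpression without and with H2O2, and abscisic acid and osmotic genes for H2O2 in the overexpressor and overexpression without H2O2. At a minimum of 10, 23 of the 30 stayed, and with none 20, with 17 of the 17 in both. Relative to genes of like mean count 28 and 16 stayed, and without concentrated reads 27 of 28 and 17. With no minimum count, the calls lost included jasmonate genes for H2O2 in wild type, at percentile 40.25, for overexpression with H2O2, at 89.6, and for the difference, at 92.45.

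TMM on genes past the filter gave 475 and 57 for H2O2 in wild type, 198 and 606 for overexpression with H2O2, and 370 and 709 for the difference, and the unshifted log2 ratio of HSFA4A with H2O2 went from 5.51 to 5.18. Relative to genes of like mean count these counts were 448 and 70, 228 and 590, and 385 and 670. Without concentrated reads, there were 41 and 296 for H2O2 in wild type, 91 and 57 for H2O2 in the overexpressor, 65 and 52 for overexpression without H2O2, 375 and 66 for overexpression with H2O2, and 954 and 89 for the difference. In the comparisons with the treated wild-type library the balance of higher and lower genes thus went opposite ways under these settings. Where median coverage had to move the same way as well, there were 8 and 294, 80 and 36, 47 and 50, and 362 and 9 for the first 4 of these comparisons. Genes with concentrated reads were left out here too. Coverage was scaled to library size, so a gene with equal median coverage above 0 counted as higher in the library with fewer scaled reads. The balance of these counts may therefore partly follow depth.

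The correlation of H2O2 ratios between genotypes, −0.0645, became −0.0882 at a minimum count of 10, −0.139 at 200 and −0.0418 without concentrated reads. That of the overexpression ratios, 0.103, turned negative at a minimum count of 10, at −0.0132, and with none, at −0.0473, and was 0.219 at 200. That of the pair sharing the untreated wild type, 0.348, became 0.423 at 10, 0.407 at 200 and 0.505 with none.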

Other observations

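The lists and genes described here were singled out after their values were seen, at the lower minimum mean count of 10, which had been set in advance. In the overexpressor, 9 genes of the response to low oxygen had a median H2O2 log2 ratio of −0.85, at percentile 0 of random lists, and 2 fell, the alcohol dehydrogenase ADH1 at −1.65 (−2.57 to −0.88) and PCO2, a plant cysteine oxidase, at −1.09 (−2.12 to −0.21). Without H2O2 the list had a median overexpression ratio of 0.54 at percentile 99.7, where ADH1 rose by 1.15 (0.44 to 1.95) and LBD41 by 1.35 (0.71 to 2.07). Both medians use the untreated overexpressor library, so they are not separate evidence. In wild type the H2O2 median was 0.18 relative to the tested genes, at percentile 56.5, and 0 of 10 genes passed 2-fold. The difference of responses had a relative median of −0.93 over 9 genes, at percentile 2.1, with 3 called downward. ADH1 rests on 21 reads in wild type, 30 in wild type with H2O2, 66 in the overexpressor and 16 in the overexpressor with H2O2.

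Carbon starvation genes, which rise when sugar runs short, had a median H2O2 ratio of 0.70 in the overexpressor, with 2 of 6 rising, and a median overexpression ratio with H2O2 of 0.89 relative to the tested genes, with 3 of 6 rising, each at percentile 100. SEN1, a senescence marker, had 1, 8, 10 and 25 reads in wild type, wild type with H2O2, the overexpressor and the overexpressor with H2O2, and AT3G15450 had 25, 53, 80 and 148. Salicylate and camalexin genes had 4 of 7 rising with H2O2 in wild type, among them PR2 with concentrated reads. The list's median was 1.14 above the tested genes, at percentile 99.5 of random lists matched on mean count. NIMIN1, a regulator of salicylate signalling, had 3 and 23 reads there and PAD3, of camalexin synthesis, 8 and 29. In that comparison all genes with a mean count of 10 to 20 had a median of 0.41, against −0.11 for all tested genes. Part of the 1.14 may thus go with the trend with count. For overexpression with H2O2 the median of this list was −0.92 relative to the tested genes, with 2 of 7 falling, at percentile 3.40, which is inside the middle 95% of random lists. It uses the same treated wild-type library. Cell division genes, 12 measured, had 1 rising with H2O2 in wild type, at percentile 87.2, and none past 2-fold for overexpression without H2O2, at percentile 7.10.

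RPS14, RPS15 and RPS19 had normalized values above 0 in every library in the authors' tables of library pairs. They were the only 3 such features without a fold in the authors' fold table. Folds for wild type with H2O2 and for the overexpressor stood there under the names in lower case, rps14, rps15 and rps19. In the tables of library pairs the names in capitals are nuclear genes. Those in lower case are plastid genes with a normalized value of 0 in every library.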
